A study of Mus musculus with 12 samples.

How the data were processed

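RNA sequencing had been done on primary hepatocytes from 6-week-old mice. The mice were either G3bp1-Flox (Flox, the controls) or carried a hepatocyte-specific G3bp1 knockout (HKO), and the cells of each genotype were given BSA or PA. That makes 4 groups of 3 libraries, 12 in all. The labels do not spell out BSA or PA, and the dose and duration are not given in the sources used here. Per the labels, RNA came from an RNeasy Plus Mini Kit and libraries from an NEBNext Ultra RNA kit, and the genome build named by the submitters is GRCm38 (mm10). The aligner, the read counter and the annotation release are not given in the sources used here.

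The deposited table holds FPKM values for 54532 genes, 1 column per library, with the gene length that the authors used as the kilobase divisor. Multiplied by that length, 100% of the values of up to 1000 reads lay within 0.01 of a whole multiple of 1 step in every library, so the number of reads per gene could be computed. These reads came to between 15.02 M and 18.42 M per library (median 16.6 M). FPKM times length in kilobases summed to between 0.9027 M and 1.175 M per library, so the authors divided by a scaled library size (13.44 M to 19.14 M) and not by the sum of the reads in genes. Of the gene identifiers, 54495 are in GENCODE M21, and 53585 of these have the same chromosome, start and end there.

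Values were used on the scale log2(FPKM + 1). Fold changes on this scale understate the change of genes near or under 1 FPKM. Genes with a mean of at least 1 FPKM over the 12 libraries were tested, 9743 in all, of which 8863 are protein-coding. One limma model (limma 3.58.1 in R 4.3.3, variance prior with a trend on the mean) gave 4 group means. From it came 5 comparisons: PA against BSA in Flox, PA against BSA in HKO, HKO against Flox in BSA, HKO against Flox in PA, and the interaction, which is the PA effect in HKO minus the PA effect in Flox. All p-values are two-sided, adjusted by Benjamini-Hochberg over the genes tested in each comparison, and genes under an adjusted p of 0.05 are said to have passed, risen or fallen. These p-values measure only the spread between these samples. Whether the libraries of 1 group came from different mice is not given in the sources used here.

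Before the data were examined, 30 gene lists, the comparisons, the test, the threshold, the rule for naming genes and most of the alternatives had been fixed. The lists cover PPARA targets and fatty acid oxidation, fatty acid synthesis, cholesterol synthesis, lipid droplets and triglyceride turnover, ATF4 and CHOP targets, endoplasmic reticulum chaperones, NF-kB targets and cytokines, acute phase proteins, the interferon response, mitochondrial calcium uptake, nuclear OXPHOS subunits, mitochondrially encoded transcripts, stress granule components, NRF2 targets and antioxidants, p53 targets and cell death, and the cell cycle. They also cover glucose metabolism, bile acid metabolism and transport, autophagy and lysosome, early response and dissociation stress, hepatocyte identity, periportal and pericentral hepatocytes, stellate cells and extracellular matrix, Kupffer cells and macrophages, liver endothelium, cholangiocytes, lymphocytes, neutrophils and cytosolic ribosomal proteins. Each list was tested with camera (limma) at a preset correlation of 0.01, adjusted over the 30 lists within each comparison. The same test with a correlation estimated from the data was an alternative. Named genes are G3bp1 and G3bp2, the 10 genes per direction with the highest fold change among those that passed and whose 3 libraries of 1 group all lay above the 3 of the other (5 per direction for the interaction), and of each list the 2 to 4 members with the highest absolute fold change among those that passed, or the 2 with the smallest p if none did. All tested members of the mitochondrial calcium uptake list were looked up too. Values of some single genes are not reported here. Predicted genes and pseudogenes were left out by their symbols.

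The alternatives fixed beforehand were a pseudocount of 0.1, no filter on low values, a filter at 5 FPKM, quantile normalization, scaling by a trimmed mean of log ratios, limma array weights, a robust variance prior, a fit with only the groups compared, a fold limit of 1 on the log2 scale, the replicate number as a block, genotype and number as a block, each library left out in turn, and for the lists an estimated correlation and the self-contained test fry. A library was left out only for the comparisons that its group enters. The default array weights gave 1 library, HKO_PA 2, a weight of 0 and did not converge. Alternatives added after the data were seen were limma-voom on the computed reads, array weights estimated gene by gene, removal of a trend with transcript length or with GC content, and omission of both HKO libraries numbered 1. Alternatives planned for a table of raw counts were not run, because the values tested are FPKM.

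The test was tested on simulated data with fold changes put into 100 genes, averaged over 10 simulations. All genes and groups were drawn with the same spread (coefficient of variation 0.146), and genes independently of each other. In the data the median SD on the log2 scale was 0.104 in Flox_BSA and 0.223 in HKO_PA. The shares below therefore hold for the simulated data and do not measure recovery or false calls in the data. A 2-fold change was recovered in 87.6% to 92.3% of genes in the 4 simple comparisons and in 52.2% in the interaction, and a 1.5-fold change in 26.1% to 39.6% and in 7.1%. The share of calls that were false was between 4.47% and 7.4%. A first version with 1 simulation gave shares of 4.59%, 9.09%, 11.3%, 5.91% and 4.92% in the order of the comparisons. After these had been seen it was replaced by the average of 10, of which it is the first. Of 200 random lists, 2% fell under an unadjusted p of 0.05 in camera. Since the simulated genes were independent, a low share was built in. It does not test the list p-values in the data, where genes can be correlated. No pair of replicate libraries was a copy: the chi-square per gene between replicates was at least 7.806.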

Results

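The data are 12 RNA-seq libraries of primary mouse hepatocytes, 3 per group: Flox with BSA, Flox with PA, HKO with BSA and HKO with PA. The series text gives the purpose as finding how G3BP1, an RNA-binding protein of stress granules, affects NASH, and the title names the mitochondrial calcium uniporter (MCU) complex. Reads in genes ranged from 15.02 to 18.42 M per library (M, 10 to the power of 6), and 16585 to 18248 genes had a value above 0. Values are FPKM as mean ± SD with n = 3, fold changes are log2 with their standard error (SE) where given, and adjusted p-values come from limma. For each gene said to have risen or fallen among the most changed, all 3 libraries of 1 group lay above all 3 of the other. The first principal component held 65.3% of the variance and parted Flox from HKO. The HKO libraries varied more: the median SD of a gene on the log2 scale was 0.104 in Flox_BSA and 0.114 in Flox_PA, against 0.21 in HKO_BSA and 0.223 in HKO_PA. On the second component (11.7%) HKO_BSA 1 lay at 26.7 and HKO_PA 1 at -34.3. Mitochondrial genes took 2.211% to 4.339% of the reads in Flox libraries and 4.1% to 8.203% in HKO libraries.

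G3bp1 (ENSMUSG00000018583, chromosome 11, 55469685 to 55504838, plus strand) was reduced in every HKO library. It measured 40.02, 37.74 and 45.72 FPKM in Flox_BSA, 39.06, 38.97 and 41.64 in Flox_PA, 7.771, 8.476 and 8.497 in HKO_BSA, and 7.027, 7.388 and 8.09 in HKO_PA. The HKO groups held 20% of the Flox level in BSA (log2 -2.19, SE 0.12, adjusted p = 3.5e-09) and 18.8% in PA (log2 -2.27, SE 0.12, adjusted p = 3.31e-09). PA left no detectable change in G3bp1 in either genotype (log2 -0.04, adjusted p = 0.887 in Flox, and log2 -0.12, adjusted p = 0.569 in HKO). The paralog G3bp2 (ENSMUSG00000029405, chromosome 5, 92052146 to 92083719, minus strand) had a mean of 2.07 ± 0.28 FPKM in Flox_BSA and 2.09 ± 0.493 in HKO_BSA, and did not pass in BSA (adjusted p = 1) or in PA (log2 0.10, adjusted p = 0.563).

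**Figure D1:**
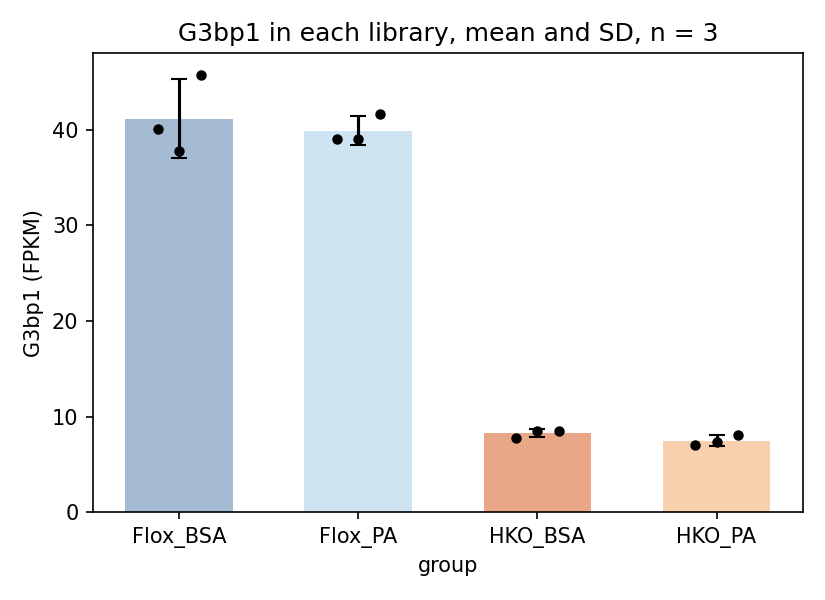
G3bp1 in FPKM (vertical axis) in the 4 groups, with bars for the mean, error bars for the SD and 1 point per library (n = 3). All 6 HKO libraries lie between 7.027 and 8.497 FPKM and all 6 Flox libraries between 37.74 and 45.72 FPKM.

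The first comparison asked what PA does in Flox hepatocytes. Plin2, which coats lipid droplets (chromosome 4, 86648386 to 86670060), rose from 81.4 ± 10.7 to 322 ± 47.2 FPKM (log2 1.97, SE 0.16, adjusted p = 2.34e-05). Hamp, the iron hormone hepcidin, rose from 38.0 ± 9.23 to 276 ± 50.3 FPKM (log2 2.84, SE 0.35, adjusted p = 0.000761). The early response factor Egr1 rose from 3.53 ± 0.331 to 16.4 ± 2.7 FPKM, and the heat shock gene Hspa1b from 0.555 ± 0.122 to 3.97 ± 0.661 FPKM. Dio3, which inactivates thyroid hormone, fell from 17.5 ± 3.97 to 2.27 ± 0.396 FPKM (log2 -2.49, SE 0.17, adjusted p = 7.59e-06), and the tight junction gene Cldn4 fell from 57.5 ± 4.47 to 13.6 ± 2.97 FPKM. Ctgf, Thbs1, Tpm2 and Cnn2, genes of matrix and actin filaments, fell too, with log2 changes of -1.57, -1.36, -1.33 and -1.24, as did the hormone gene Fgf21 (log2 -1.31).

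By list, a minority of the lipid and stress genes rose in Flox with PA. Of 24 cholesterol synthesis genes 5 rose, none fell and 19 did not pass (12 rose when adjusted over the list alone), among them Dhcr7 (log2 1.33) and Mvd (log2 0.92); the list passed at adjusted p = 6.72e-08, but had adjusted p = 0.14 with an estimated correlation. Of 29 NRF2 targets and antioxidants 6 rose, none fell and 23 did not pass (8 rose adjusted over the list alone), with Cbr3 (log2 1.12) and Gclm (log2 0.79) among them; the list had adjusted p = 1.63e-07, and adjusted p = 0.14 with an estimated correlation. Of 15 early response and dissociation stress genes 4 rose and 11 did not pass (7 rose adjusted over the list alone). Early response and dissociation stress genes as a list had adjusted p = 1.48e-08 and adjusted p = 0.206 with an estimated correlation. Of 22 endoplasmic reticulum chaperone genes 5 rose and 17 did not pass (5 rose and 1 fell adjusted over the list alone), among them Derl3 (log2 1.83), Creld2 (log2 1.22) and Herpud1 (log2 1.13). Endoplasmic reticulum chaperones as a list had adjusted p = 0.00606 and adjusted p = 0.293 with an estimated correlation. Among 18 lipid droplet genes 3 rose, 1 fell and 14 did not pass (5 rose and 1 fell adjusted over the list alone): Hilpda rose (log2 0.95) with Plin2, and G0s2, an inhibitor of triglyceride breakdown, fell from 67.6 ± 6.89 to 31.2 ± 3.33 FPKM. That list had adjusted p = 0.000413, and adjusted p = 0.295 with an estimated correlation.

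Of 24 NF-kB targets and cytokines 3 rose and 21 did not pass in Flox (9 rose and 1 fell adjusted over the list alone), namely Cxcl1 (log2 1.14), Tnf (log2 0.77) and Cxcl2 (log2 0.63). NF-kB targets and cytokines as a list had adjusted p = 0.00189 and adjusted p = 0.293 with an estimated correlation. Of 16 macrophage markers 2 fell and 14 did not pass (4 fell adjusted over the list alone), Vsig4 (log2 -0.93) and Timd4 (log2 -0.55). Macrophage markers as a list had adjusted p = 0.00189 and adjusted p = 0.379 with an estimated correlation. PPARA targets and fatty acid oxidation (4 of 27 rose, 1 fell; 6 and 1 adjusted over the list alone) had adjusted p = 0.0293, and adjusted p = 0.382 with an estimated correlation. PPARA targets lost the call without Flox_BSA 2 (adjusted p = 0.0984) or Flox_PA 2 (adjusted p = 0.0586), without both HKO libraries numbered 1 (0.0747) and with the length trend removed (0.0572). Fatty acid synthesis (1 of 17 rose, Thrsp; 1 adjusted over the list alone) had adjusted p = 0.00911, and adjusted p = 0.461 with an estimated correlation. Autophagy and lysosome (1 of 23 rose; 1 adjusted over the list alone) had adjusted p = 0.0286, and adjusted p = 0.461 with an estimated correlation. Autophagy and lysosome lost the call without Flox_BSA 2 (adjusted p = 0.0554), Flox_PA 3 (adjusted p = 0.0837) or both HKO libraries numbered 1 (0.0543). Pericentral hepatocyte genes (0 of 9 passed; 2 rose adjusted over the list alone) had adjusted p = 0.0114, adjusted p = 0.293 with an estimated correlation, and 0.0512 under quantile normalization. Mitochondrially encoded transcripts (0 of 13 passed, and 0 adjusted over the list alone; median log2 -0.29) had adjusted p = 0.033, and adjusted p = 0.588 with an estimated correlation. Mitochondrially encoded transcripts lost the call without Flox_BSA 3 (adjusted p = 0.32) or Flox_PA 3 (adjusted p = 0.0575) and with the GC trend removed (0.574). Under the self-contained test fry 4 lists lost their call in Flox, fatty acid synthesis (adjusted p = 0.165), mitochondrially encoded transcripts (0.452), autophagy and lysosome (0.123) and macrophage markers (0.123).

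In all, 215 of 9743 genes passed in Flox, 126 higher and 89 lower with PA, 26 and 16 of them by at least 2-fold. In 39% of genes the 3 PA libraries lay entirely on 1 side of the 3 BSA libraries, where chance gives 10%. The count depended on the libraries and on the estimate of the spread. With genotype and number as a block the count was 110. It was 79 without Flox_BSA 1, 85 without Flox_BSA 2, 107 without Flox_BSA 3, 64 without Flox_PA 2 and 79 without Flox_PA 3, against 1356 without both HKO libraries numbered 1 and 1543 with only the Flox libraries in the fit. It was 142 (97 higher, 45 lower) with a pseudocount of 0.1, 129 (92 and 37) with a filter at 5 FPKM, 357 with the GC trend removed, 4210 with default and 3641 with gene-by-gene array weights, and 42 with the fold limit; without a filter 111 rose and 126 fell. Of 52 named genes that passed, 28 did so with each Flox library left out in turn, Plin2, Hamp, Egr1, Hspa1b, Dio3, Cldn4 and Ctgf among them. Single HKO libraries, which share the estimate of the spread, were not left out here.

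The second comparison asked what PA does in HKO hepatocytes. Plin2 rose from 207 ± 29.1 to 780 ± 14.8 FPKM (log2 1.92, SE 0.16, adjusted p = 1.89e-05) and Hamp from 5.29 ± 3.5 to 83.6 ± 31.1 FPKM (log2 3.84, SE 0.35, adjusted p = 4.58e-05). Chemokines and cytokines rose: Ccl2 from 59.7 ± 15.6 to 269 ± 79.8 FPKM, Cxcl1 from 18.5 ± 4.96 to 74.2 ± 6.79, Cxcl2 from 10.9 ± 1.98 to 42.8 ± 1.56, and Il23a from 0.794 ± 0.157 to 6.91 ± 0.68. The heat shock genes Hspa1a (log2 2.07, SE 0.12) and Hspa1b (log2 2.30, SE 0.17) rose. Dio3 fell from 8.33 ± 0.936 to 1.43 ± 0.311 FPKM, Fn1, which encodes fibronectin, from 252 ± 55.2 to 100 ± 45.8, Fasn, the fatty acid synthase, from 48.0 ± 11.3 to 19.7 ± 8.6, the cyclin gene Ccnd1 from 3.65 ± 0.217 to 1.05 ± 0.252, and the macrophage growth factor gene Csf1 from 13.2 ± 0.945 to 5.58 ± 1.42 FPKM.

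NF-kB targets and cytokines were the list with the most members past the test in HKO with PA. Of 24 members 14 rose, 1 fell (Csf1) and 9 did not pass (19 rose and 1 fell adjusted over the list alone). NF-kB targets and cytokines as a list had adjusted p = 1.57e-14 and still at adjusted p = 0.0403 with an estimated correlation. The macrophage markers Marco (8.39 ± 2.83 to 16.8 ± 2.64 FPKM) and Lyz2 (39.9 ± 4.65 to 63.5 ± 9.55) rose beside them, while their list did not pass (2 of 16 rose, and 2 adjusted over the list alone; adjusted p = 0.237). Of 15 early response and dissociation stress genes 6 rose and 9 did not pass (7 adjusted over the list alone). Early response and dissociation stress genes as a list had adjusted p = 1.56e-07 and adjusted p = 0.304 with an estimated correlation. Of 27 PPARA targets and fatty acid oxidation genes 4 rose, 1 fell and 22 did not pass (7 and 1 adjusted over the list alone), among them Creb3l3 (log2 1.67), Pdk4 (log2 0.97) and Acadl (log2 0.92). PPARA targets as a list had adjusted p = 0.000262 and adjusted p = 0.304 with an estimated correlation. Acute phase proteins (2 of 21 rose, Hamp and Lcn2; 6 rose and 1 fell adjusted over the list alone) had adjusted p = 0.000458, and adjusted p = 0.39 with an estimated correlation; without both HKO libraries numbered 1 the value was 0.121. NRF2 targets (2 of 29 rose, the metallothioneins Mt1 and Mt2, and Gclc fell; 7 and 2 adjusted over the list alone) had adjusted p = 0.00206, adjusted p = 0.344 with an estimated correlation, and 0.105 under quantile normalization.

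Few lipid synthesis genes passed in HKO with PA. Of 17 fatty acid synthesis genes 2 fell (Fasn, log2 -1.32, and Mlxipl, log2 -0.70) and 15 did not pass (5 fell adjusted over the list alone). Fatty acid synthesis as a list had adjusted p = 0.0108 and adjusted p = 0.575 with an estimated correlation. Fatty acid synthesis lost the call without HKO_PA 1 (adjusted p = 0.215), without HKO_BSA 2 (adjusted p = 0.0516) and without both HKO libraries numbered 1 (adjusted p = 0.412). Of 24 cholesterol synthesis genes none passed (2 rose adjusted over the list alone). Cholesterol synthesis as a list had adjusted p = 0.0234 and adjusted p = 0.459 with an estimated correlation. Cholesterol synthesis lost the call without HKO_BSA 1 (0.138), HKO_BSA 3 (0.0621), HKO_PA 2 (0.0828) or HKO_PA 3 (0.24). Of 18 lipid droplet genes 4 rose, 1 fell (Mgll, log2 -0.70) and 13 did not pass (6 and 1 adjusted over the list alone); G0s2 rose from 22.9 ± 6.64 to 40.3 ± 6.61 FPKM. This list had adjusted p = 0.0159 and adjusted p = 0.535 with an estimated correlation, and was lost without HKO_BSA 2 (0.0651), HKO_BSA 3 (0.0621) or HKO_PA 3 (0.0714). No member of the cytosolic ribosomal protein list (75 tested, median log2 0.33) or of the nuclear OXPHOS list (49 tested, median log2 0.27) passed, over all genes or adjusted over the list alone (0 members each). The lists had adjusted p = 2.01e-10 and 1e-04, with adjusted p = 0.572 and adjusted p = 0.726 with an estimated correlation, and the OXPHOS call was lost without HKO_PA 1 (adjusted p = 0.131). Across the 9743 genes the change with PA in HKO ran against transcript length (Spearman -0.43; genes are not independent replicates), and HKO_PA 1 had the highest share of reads in ribosomal protein genes, 9.603% against 5.842% to 7.415% in the other HKO libraries. The self-contained test fry did not call 4 of these lists, fatty acid synthesis (adjusted p = 0.197), cholesterol synthesis (0.119), OXPHOS (0.304) and ribosomal proteins (0.197).

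In all, 286 genes passed in HKO, 164 higher and 122 lower, 41 and 19 of them by at least 2-fold, and 18.2% of genes had groups that did not overlap, where chance gives 10%. The count was 129 without HKO_BSA 2, 143 without HKO_BSA 3, 167 without HKO_PA 1, 141 without HKO_PA 2 and 776 (247 higher, 529 lower) without HKO_PA 3. It was 679 without both HKO libraries numbered 1, 42 with only the HKO libraries in the fit, 144 without a filter, 687 with the GC trend removed, 117 with default and 1532 (661 higher, 871 lower) with gene-by-gene array weights, and 60 with the fold limit. With genotype and number as a block the count was 113. Of 50 named genes that passed, 33 did so with each HKO library left out, Plin2, Hamp, Ccl2, Cxcl1, Cxcl2, Il23a, Hspa1a, Hspa1b, Dio3, Ccnd1 and Csf1 among them.

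**Figure D2:**
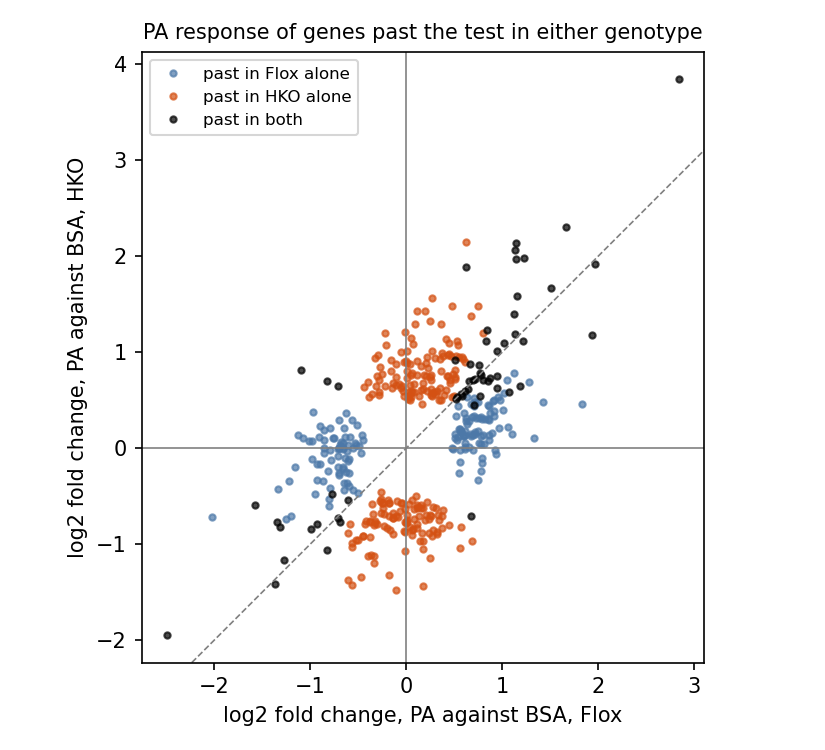
Log2 fold change of PA against BSA in Flox (horizontal axis) and in HKO (vertical axis), 1 point per gene past the test in either genotype, with a dashed line of slope 1. Of these genes 41 rose in both, 13 fell in both and 4 moved in opposite directions.

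The PA responses of the genotypes shared genes. Of the genes that rose, 41 did so in both genotypes (2.12 expected if the calls were independent), among them Plin2, Hamp, Hspa1a, Hspa1b, Creb3l3, Creld2, Herpud1, Cxcl1 and Cxcl2, and 13 fell in both (1.11 expected), among them Dio3, Thbs1, Vil1 and Fgf21. The genes that rose in Flox had a median log2 change of 0.77 there and 0.37 in HKO, and those that fell had -0.71 and -0.11. The genes that rose in HKO had a median of 0.76 there and 0.28 in Flox, and those that fell -0.76 and -0.10. A smaller change where a gene was not selected is also what selection gives, so these medians do not test a difference. The slope of HKO on Flox was 0.597 over 443 genes past in either, and ranged from 0.492 with quantile normalization to 0.733 with a pseudocount of 0.1. Noise in the Flox changes can lower such a slope, so it does not test a difference either.

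The third comparison asked what loss of G3bp1 does in BSA. Macrophage genes were far lower in HKO: all 16 tested macrophage markers fell (16 adjusted over the list alone), with a median log2 change of -4.19. Cd5l (chromosome 3, 87357881 to 87371073) fell from 297 ± 7.96 to 7.15 ± 2.46 FPKM (log2 -5.23, SE 0.19, adjusted p = 1.55e-10), Marco from 209 ± 3.19 to 8.39 ± 2.83, and Ctss from 109 ± 13.7 to 3.51 ± 1.21 FPKM. The MHC class II genes Cd74, H2-Aa and H2-Ab1 fell too: Cd74 went from 320 ± 15.3 to 4.46 ± 1.58 FPKM, H2-Aa from 70.6 ± 3.86 to 1.04 ± 0.76 and H2-Ab1 from 65.3 ± 5.49 to 0.949 ± 0.713. The macrophage list had adjusted p = 6.07e-29, and 0.0127 with an estimated correlation.

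**Figure D3:**
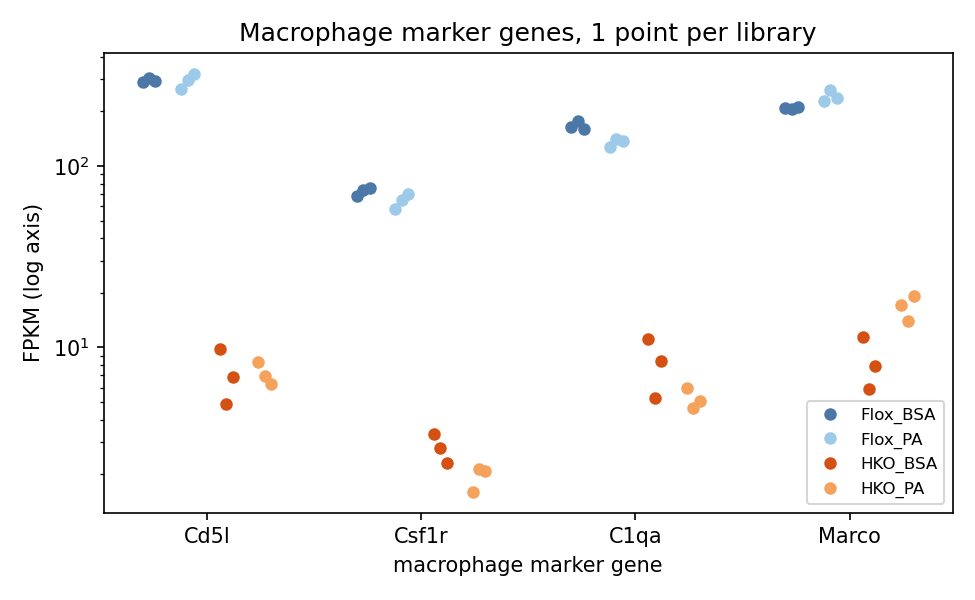
FPKM (log vertical axis) of the macrophage markers Cd5l, Csf1r, C1qa and Marco, 1 point per library, coloured by group. Mean Cd5l was 297 FPKM in Flox_BSA, 296 in Flox_PA, 7.15 in HKO_BSA and 7.15 in HKO_PA.

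Inflammatory genes fell with the macrophage markers in BSA. Of 27 interferon response genes 26 fell and 1 did not pass (26 adjusted over the list alone), for example Ifi27l2a (70.1 ± 7.46 to 1.19 ± 0.812 FPKM), Oas1a (33.2 ± 1.9 to 1.23 ± 0.386) and Zbp1 (23.5 ± 2.79 to 2.21 ± 0.71). Interferon response genes as a list had adjusted p = 1.17e-24 and 0.0127 with an estimated correlation. Of 24 NF-kB targets and cytokines 19 fell, 2 rose and 3 did not pass (20 and 2 adjusted over the list alone), with Ccl7 (log2 -3.76), Il1b (log2 -3.16) and Tnf (log2 -2.31). NF-kB targets and cytokines as a list had adjusted p = 6.68e-14 and 0.0171 with an estimated correlation. Of 21 acute phase proteins 8 fell, 1 rose and 12 did not pass (11 and 1 adjusted over the list alone); Lcn2 fell from 1630 ± 134 to 103 ± 14.6 FPKM, and Saa3, Hamp and Orm2 had log2 changes of -2.77, -2.75 and -2.71. This list had adjusted p = 0.000588, and adjusted p = 0.21 with an estimated correlation. The 2 neutrophil genes tested fell (2 adjusted over the list alone; 9 more lay below the filter), S100a8 (log2 -3.56) and Csf3r (log2 -2.27). Neutrophil genes as a list had adjusted p = 0.000113 and 0.0287 with an estimated correlation; Ccl5 fell, the only lymphocyte gene tested, since 15 lay below the filter (log2 -3.56; 1 adjusted over the list alone). The lymphocyte list, here Ccl5 alone, had adjusted p = 0.00602 and adjusted p = 0.0719 with an estimated correlation. Endothelial markers moved less: 6 of 9 fell and 3 did not pass (6 adjusted over the list alone), median log2 -0.49, with Stab1 at -1.71 and Cdh5 at -1.13. Endothelial markers as a list had adjusted p = 0.00401 and adjusted p = 0.204 with an estimated correlation. Of 6 stellate cell and matrix genes 3 fell (3 adjusted over the list alone), Ecm1 (log2 -2.01), Tgfb1 (log2 -1.80) and Sparc (log2 -0.47). Stellate and matrix genes as a list had adjusted p = 0.0399 and adjusted p = 0.3 with an estimated correlation. Stellate and matrix genes lost the call without HKO_BSA 2 (0.0571) or HKO_BSA 3 (0.0664), and with replicate number as a block (0.0553).

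Major urinary protein genes rose most in BSA, secreted lipid-binding proteins made by hepatocytes. Mup17 (chromosome 4, 61591929 to 61595871) went from 0.274 ± 0.132 to 478 ± 229 FPKM (log2 8.45, SE 0.34, adjusted p = 2.83e-10) and Mup7 from 109 ± 14.4 to 1638 ± 504; these genes are near-identical copies, so the values of single members are uncertain. The sum over 21 Mup genes was 954.8 ± 60.7 FPKM in Flox_BSA and 7405 ± 1980 in HKO_BSA, and 681.8 ± 48.8 in Flox_PA and 8499 ± 3110 in HKO_PA. The calcium-binding protein genes S100a6 (7.90 ± 0.22 to 117 ± 18.1 FPKM) and S100a4 (0.542 ± 0.5 to 9.44 ± 1.45) rose, as did the drug-metabolizing gene Cyp2b10 (4.52 ± 0.8 to 35.7 ± 5.97).

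Hepatocyte identity, cholesterol synthesis and PPARA target lists moved up with the knockout in BSA. Macrophage markers were far lower in HKO, so a larger share of hepatocytes among these cells could raise hepatocyte genes as well. That was not tested for these lists, nor for the zonal, bile acid, glucose and mitochondrial lists, in BSA or in PA. Of 23 hepatocyte identity genes 9 rose and 14 did not pass (10 adjusted over the list alone), among them Apoc3 (log2 1.29), Foxa2 (log2 1.20) and Serpina1c (log2 1.14). Hepatocyte identity as a list had adjusted p = 4.33e-05 and 0.0422 with an estimated correlation. Within HKO_BSA, Alb was 4091 FPKM in HKO_BSA 1, against 15610 and 14050 in HKO_BSA 2 and 3 and 4135 to 4521 in Flox_BSA, and did not pass (adjusted p = 0.0644). Of 24 cholesterol synthesis genes 13 rose and 11 did not pass (15 adjusted over the list alone), with Cyp51 (log2 1.04) and Pmvk (log2 1.03). Cholesterol synthesis as a list had adjusted p = 2.55e-06 and adjusted p = 0.0694 with an estimated correlation. Of 27 PPARA targets and fatty acid oxidation genes 10 rose, 2 fell and 15 did not pass (10 and 2 adjusted over the list alone): the fatty acid hydroxylase Cyp4a14 rose from 1.25 ± 0.371 to 13.1 ± 5.69 FPKM and Cyp4a10 from 4.88 ± 0.729 to 23.9 ± 6.57. PPARA targets as a list had adjusted p = 0.000427 and adjusted p = 0.11 with an estimated correlation. Plin2 rose (log2 1.33) and G0s2 and the fatty acid transporter gene Cd36 fell (log2 -1.55 and -1.36) within a lipid droplet list that did not pass (5 of 18 rose, 3 fell; 8 and 3 adjusted over the list alone; adjusted p = 0.113). Fatty acid synthesis did not pass either (3 of 17 rose, 1 fell; 3 and 1 adjusted over the list alone; adjusted p = 0.104).

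Zonal and bile acid genes rose in part in BSA. Periportal genes (6 of 10 rose, 1 fell; 6 and 1 adjusted over the list alone) had adjusted p = 0.017, and adjusted p = 0.0952 with an estimated correlation; Hamp2 rose (log2 2.59), while Ctsc, a lysosomal protease also made by immune cells, fell (log2 -3.70). Pericentral genes (5 of 9 rose; 5 adjusted over the list alone), such as Cyp2a5 (log2 1.98) and Cyp2e1 (log2 1.05), had adjusted p = 0.00531, and adjusted p = 0.11 with an estimated correlation. Bile acid metabolism (4 of 13 rose, 1 fell; 6 and 2 adjusted over the list alone), with the uptake transporter gene Slc10a1 at log2 1.76, had adjusted p = 0.0339, and adjusted p = 0.11 with an estimated correlation. Bile acid metabolism lost the call without HKO_BSA 2 (adjusted p = 0.0787). Glucose metabolism (5 of 15 rose, 3 fell; 7 and 3 adjusted over the list alone), with Igfbp1 at log2 2.47 and the glucose-6-phosphatase gene G6pc at 2.10, had adjusted p = 0.0477, and adjusted p = 0.3 with an estimated correlation. Glucose metabolism lost the call without Flox_BSA 1 (0.057), HKO_BSA 1 (0.0871) or HKO_BSA 2 (0.0595), without both HKO libraries numbered 1 (0.148), under quantile normalization (0.194) and with the length trend removed (0.0509). The same call was lost with replicate number as a block (0.0733). Cholangiocyte genes (3 of 4 rose; 3 adjusted over the list alone) had adjusted p = 0.0264, and adjusted p = 0.11 with an estimated correlation. Cell cycle genes (3 of 11 rose; 6 adjusted over the list alone), Mcm5, Tyms and Pcna, had adjusted p = 0.00799, and adjusted p = 0.159 with an estimated correlation.

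Mitochondrial transcripts rose in HKO in BSA. Of 13 mitochondrially encoded transcripts 12 rose and 1 did not pass (13 adjusted over the list alone), median log2 1.29, with mt-Cytb at 3654 ± 1097 and 9905 ± 4077 FPKM. Mitochondrially encoded transcripts as a list had adjusted p = 6.85e-06 and adjusted p = 0.228 with an estimated correlation. The share of reads in these genes in HKO_BSA was 4.1% in HKO_BSA 1, 7.909% in HKO_BSA 2 and 8.203% in HKO_BSA 3. Of 49 nuclear OXPHOS genes 14 rose and 35 did not pass (25 adjusted over the list alone), with Uqcrb (log2 0.96) and Cox7b (log2 0.83). OXPHOS genes as a list had adjusted p = 1.92e-07 and adjusted p = 0.303 with an estimated correlation. In the mitochondrial calcium uptake list 1 of 14 genes fell and 13 did not pass (1 adjusted over the list alone), and the list did not pass (adjusted p = 0.726; median log2 0.03, mean -0.11). The gene that fell was Mcub, a subunit that dampens the uniporter (2.59 ± 0.225 to 0.325 ± 0.124 FPKM, log2 -1.44, SE 0.11, adjusted p = 2.51e-07), beside the macrophage markers. Mcu itself had 4.81 ± 0.41 and 6.38 ± 0.28 FPKM (log2 0.34, SE 0.13, adjusted p = 0.0812) and Smdt1 log2 0.06 (adjusted p = 0.862).

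Among the other lists in BSA, stress granule components (4 of 23 fell; 4 adjusted over the list alone), with Eif2ak2 at log2 -1.02 and Pabpc1 at -0.49, had adjusted p = 0.0207, and adjusted p = 0.225 with an estimated correlation. Stress granule components lost the call without HKO_BSA 1 (adjusted p = 0.0752) and with the length trend removed (adjusted p = 0.124). ATF4 and CHOP targets (5 of 22 fell, 1 rose; 8 and 1 adjusted over the list alone), with Nupr1 at log2 -0.68 and Chac1 at -0.62, had adjusted p = 0.0171, and adjusted p = 0.228 with an estimated correlation. Autophagy and lysosome genes (7 of 23 fell, 2 rose; 10 and 2 adjusted over the list alone), with Hexa at log2 -1.01 and Ulk1 at 1.32, had adjusted p = 0.0399, and adjusted p = 0.404 with an estimated correlation. Autophagy and lysosome lost the call without Flox_BSA 3 (0.0892), HKO_BSA 1 (0.0638) or HKO_BSA 3 (0.0549), and with the length trend removed (0.052). Cytosolic ribosomal proteins (0 of 75 passed, and 0 adjusted over the list alone; median log2 0.16) had adjusted p = 0.017, and adjusted p = 0.674 with an estimated correlation. Ribosomal proteins lost the call without HKO_BSA 1 (0.106) or HKO_BSA 3 (0.0549) and with the length trend removed (0.223) or with fry (0.336), and the median turned to -0.02 under quantile normalization. Endoplasmic reticulum chaperones (5 of 22 rose; 5 adjusted over the list alone; adjusted p = 0.0503), NRF2 targets (7 of 29 rose, 2 fell; 8 and 2 adjusted over the list alone; adjusted p = 0.276), p53 targets and cell death (2 of 20 rose, 5 fell; 2 and 5 adjusted over the list alone; adjusted p = 0.169) and early response genes (2 of 15 fell; 2 adjusted over the list alone; adjusted p = 0.726) did not pass as lists.

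In all, 1994 genes passed in BSA, 938 higher and 1056 lower in HKO, 180 and 500 of them by at least 2-fold, and 37.7% of genes had groups that did not overlap, where chance gives 10%. The count was 1329 without Flox_BSA 1, 3579 without both HKO libraries numbered 1, 1062 (595 higher, 467 lower) with a filter at 5 FPKM, 6016 with default and 5764 with gene-by-gene array weights, and 680 with the fold limit. Without a filter 970 were higher and 1744 lower. Of 121 named genes that passed, 97 did so with each BSA library left out, all the Mup, macrophage, interferon and MHC class II genes named for BSA among them.

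The fourth comparison asked what loss of G3bp1 does in PA. The same groups led: all 16 macrophage markers fell (16 adjusted over the list alone), median log2 -3.41, among them Csf1r (64.2 ± 5.87 to 1.94 ± 0.293 FPKM) and C1qa (135 ± 7.19 to 5.20 ± 0.666). Macrophage markers as a list had adjusted p = 7.03e-21 and 0.0376 with an estimated correlation. Mup17 (0.433 ± 0.171 to 443 ± 221 FPKM), S100a6 (3.63 ± 0.602 to 84.2 ± 19.5) and Hamp2 (6.99 ± 2.1 to 67.7 ± 22.5) rose. Plin2, already raised by PA, was higher still in HKO (322 ± 47.2 and 780 ± 14.8 FPKM, log2 1.28, SE 0.16, adjusted p = 2.66e-05). Fasn fell from 57.2 ± 8.16 to 19.7 ± 8.6 FPKM, and Dgat2, the last step of triglyceride synthesis, fell from 200 ± 31 to 60.6 ± 8.6 (log2 -1.70, SE 0.20, adjusted p = 2.36e-05).

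Interferon and cytokine genes fell with the macrophage markers in PA as well. Of 27 interferon response genes 26 fell and 1 did not pass (26 adjusted over the list alone). Interferon response genes as a list had adjusted p = 5.08e-17 and 0.0402 with an estimated correlation. Of 24 NF-kB targets and cytokines 17 fell, 2 rose and 5 did not pass (17 and 2 adjusted over the list alone), with Ccl7 at log2 -2.76 and Tnf at -2.30 but Ccl20 at 1.73. As a list, NF-kB targets and cytokines had adjusted p = 1.08e-06 and adjusted p = 0.0918 with an estimated correlation. Both neutrophil genes fell (2 adjusted over the list alone; adjusted p = 0.000577, and adjusted p = 0.0651 with an estimated correlation), as did Ccl5 of the lymphocyte list (1 adjusted over the list alone; adjusted p = 0.0387, and adjusted p = 0.179 with an estimated correlation; without HKO_PA 3, 0.0574; with the GC trend removed, 0.078). Acute phase proteins (9 of 21 fell, 2 rose; 9 and 2 adjusted over the list alone; adjusted p = 0.0557), liver endothelium (3 of 9 fell; 3 adjusted over the list alone; adjusted p = 0.217), stellate cell and matrix genes (3 of 6 fell, 1 rose; 3 and 1 adjusted over the list alone; adjusted p = 0.248) and cholangiocytes (3 of 4 rose; 4 adjusted over the list alone; adjusted p = 0.0522) did not pass as lists. Of 23 autophagy and lysosome genes 11 fell, 3 rose and 9 did not pass (13 and 3 adjusted over the list alone), among them Psap (348 ± 37.5 to 116 ± 46.2 FPKM) and Hexa (log2 -1.26). Autophagy and lysosome as a list had adjusted p = 0.0081 and adjusted p = 0.463 with an estimated correlation.

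Mitochondrial and ribosomal protein transcripts rose in HKO in PA. All 13 mitochondrially encoded transcripts rose (13 adjusted over the list alone), median log2 1.76. Mitochondrially encoded transcripts as a list had adjusted p = 3.97e-07 and adjusted p = 0.318 with an estimated correlation. Of 49 nuclear OXPHOS genes 33 rose and 16 did not pass (36 adjusted over the list alone), median log2 0.65, with Uqcrc2 (log2 1.41) and Ndufa1 (log2 1.25). OXPHOS genes as a list had adjusted p = 2.22e-10 and adjusted p = 0.44 with an estimated correlation. Of 75 cytosolic ribosomal proteins 45 rose and 30 did not pass (47 adjusted over the list alone), median log2 0.59, with Rps4x (324 ± 14.1 to 774 ± 205 FPKM) and Rpl6 (274 ± 35.7 to 632 ± 145). Ribosomal proteins as a list had adjusted p = 4.03e-11 and adjusted p = 0.468 with an estimated correlation. Across genes the change ran against transcript length (Spearman -0.32). With a length trend fitted on genes outside these lists removed, the medians were 0.40 for ribosomal proteins (adjusted p = 1.36e-07) and 0.42 for OXPHOS (adjusted p = 1.62e-08), and without HKO_PA 1 they were 0.37 (adjusted p = 8.53e-09) and 0.44 (adjusted p = 7.59e-10).

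In the mitochondrial calcium uptake list 3 of 14 genes fell in PA and 11 did not pass (3 adjusted over the list alone): Mcub (3.24 ± 0.263 to 0.276 ± 0.11 FPKM, log2 -1.73, SE 0.11, adjusted p = 4.11e-08), the sodium-calcium exchanger gene Slc8b1 (17.6 ± 1.56 to 9.82 ± 3.97, log2 -0.85, SE 0.25, adjusted p = 0.0174) and the mitochondrial protease gene Afg3l2 (45.8 ± 6.46 to 26.0 ± 7.16, log2 -0.82, SE 0.18, adjusted p = 0.00388). Of all tested genes 35.7% passed in this comparison, a higher share than 3 of 14, so this count is no result about the list. Mcu (log2 0.10, adjusted p = 0.568) and Micu2 (log2 0.28, adjusted p = 0.133) did not pass, nor did the list (adjusted p = 0.794, median log2 0.03, mean -0.16). With PA none of the 14 genes passed in Flox (0 adjusted over the list alone; list adjusted p = 0.556) or in HKO (0 adjusted over the list alone; list adjusted p = 0.994).

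Lipid and hepatocyte lists moved in HKO in PA as follows, with the same limit on the hepatocyte share as in BSA. Of 27 PPARA targets and fatty acid oxidation genes 17 rose and 10 did not pass (19 adjusted over the list alone), with Cyp4a14 (1.14 ± 0.122 to 14.4 ± 1.36 FPKM) and Creb3l3 (log2 1.11). PPARA targets as a list had adjusted p = 1.19e-05 and adjusted p = 0.0918 with an estimated correlation. Of 24 cholesterol synthesis genes 12 rose, 3 fell and 9 did not pass (12 and 3 adjusted over the list alone), with Msmo1 (log2 1.40) and Sc5d (log2 1.34). Cholesterol synthesis as a list had adjusted p = 0.0198 and adjusted p = 0.404 with an estimated correlation. Cholesterol synthesis lost the call without HKO_PA 3 (adjusted p = 0.0975) and under quantile normalization (0.0551). Hepatocyte identity (11 of 23 rose, 1 fell; 12 and 1 adjusted over the list alone), with Cyp3a11 at log2 1.56 and Apoc3 at 1.31, had adjusted p = 0.00231, adjusted p = 0.123 with an estimated correlation, and 0.0554 under quantile normalization. Fatty acid synthesis (6 of 17 fell, 1 rose; 6 and 1 adjusted over the list alone; adjusted p = 0.129), lipid droplets (4 of 18 rose, 3 fell; 5 and 3 adjusted over the list alone; adjusted p = 0.403), glucose metabolism (5 of 15 rose, 6 fell; 6 and 6 adjusted over the list alone; adjusted p = 0.794; median log2 -0.08, mean 0.13), bile acid metabolism (5 of 13 rose, 1 fell; 6 and 2 adjusted over the list alone; adjusted p = 0.305), and periportal (4 of 10 rose, 1 fell; 4 and 2 adjusted over the list alone; adjusted p = 0.332) and pericentral genes (3 of 9 rose, 1 fell; 3 and 1 adjusted over the list alone; adjusted p = 0.233) did not pass as lists. Nor did stress granule components (7 of 23 fell; 7 adjusted over the list alone; adjusted p = 0.145), of which Usp10, a G3BP1 partner, fell from 22.6 ± 2.09 to 12.1 ± 4.08 FPKM.

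**Figure D4:**
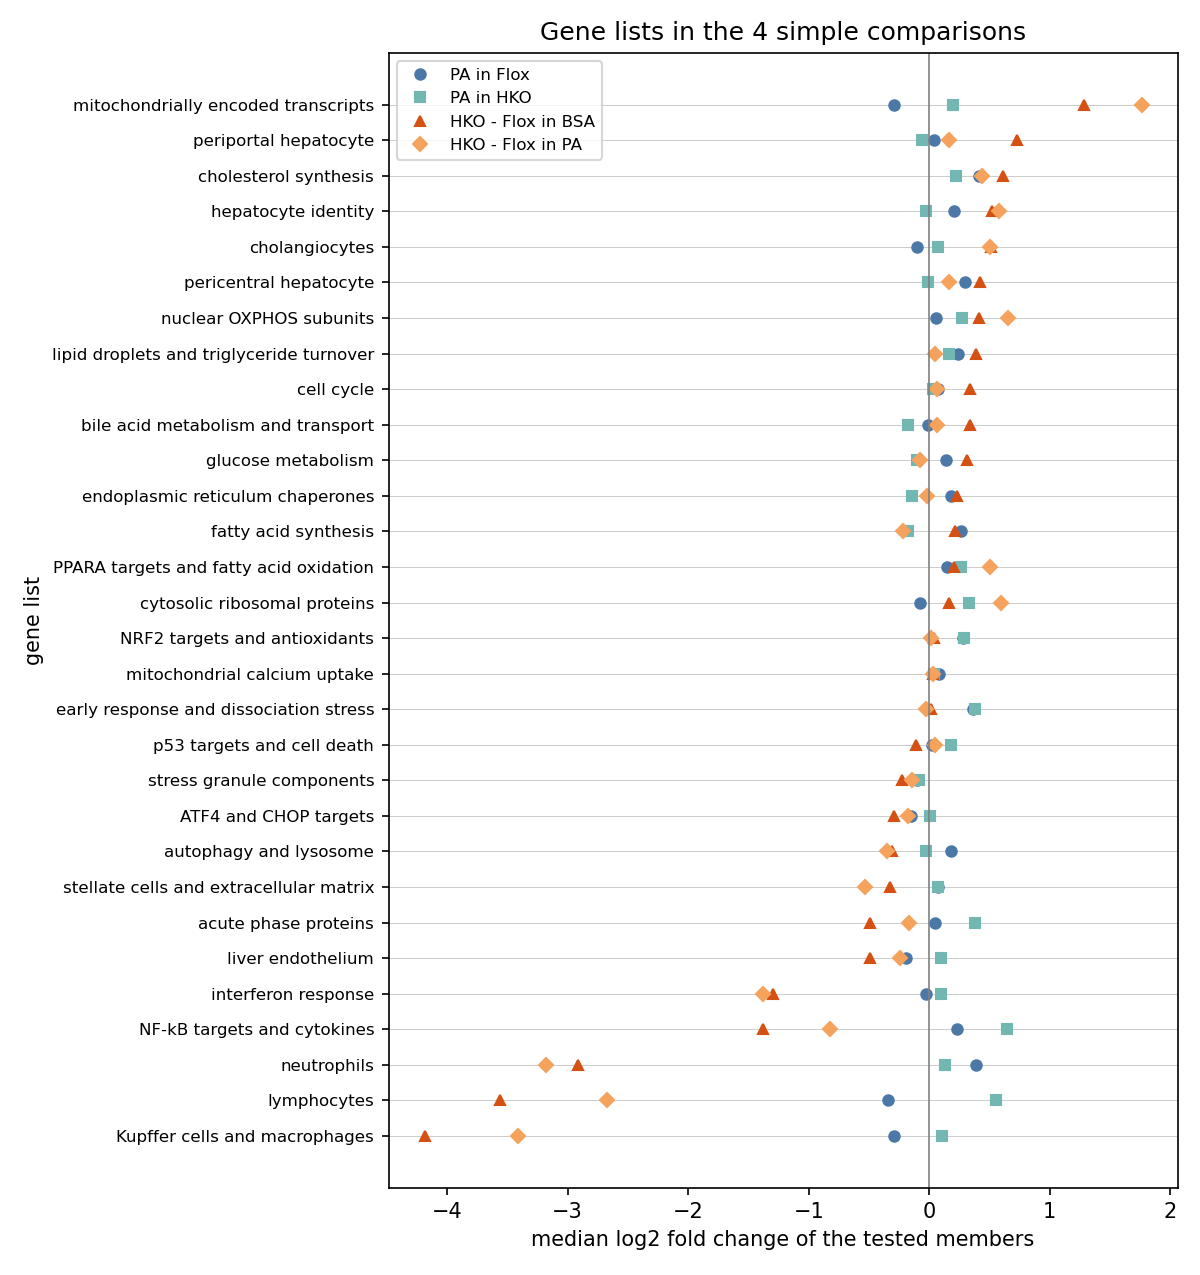
Median log2 fold change of the tested members (horizontal axis) of the 30 gene lists in the 4 simple comparisons, 1 symbol per comparison, ordered by HKO against Flox in BSA. The macrophage list lies at -4.19 in BSA and -3.41 in PA, and the mitochondrially encoded transcripts at 1.29 and 1.76.

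In all, 3475 genes passed in PA, 1644 higher and 1831 lower in HKO, 319 and 545 of them by at least 2-fold, and 52% of genes had groups that did not overlap, where chance gives 10%. The count was 2280 without Flox_PA 3, 2307 with default array weights and 864 with the fold limit. Of 126 named genes that passed, 110 did so with each PA library left out. The genotype effects in BSA and PA shared 554 genes higher (158 expected if independent) and 793 lower (198 expected), with 12 in opposite directions, and the slope of PA on BSA was 0.919 over 4110 genes past in either.

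The fifth comparison asked whether PA acted differently in HKO and Flox. G0s2 fell with PA in Flox and rose in HKO (interaction log2 1.91, SE 0.27, adjusted p = 0.0129). Gclc, the first enzyme of glutathione synthesis, measured 87.2 ± 4.49 and 140 ± 7.71 FPKM in Flox with BSA and PA, and 144 ± 24.8 and 87.1 ± 8.41 in HKO (log2 -1.39, adjusted p = 0.0129). The autophagy kinase gene Ulk1 measured 4.04 ± 0.22 and 6.52 ± 1.13 FPKM in Flox, and 11.8 ± 2.79 and 5.22 ± 1.32 in HKO (log2 -1.61, adjusted p = 0.0234). Adam8 (log2 -1.61, adjusted p = 0.0129) and Csf1 (log2 -1.39, adjusted p = 0.0208) fell with PA in HKO. Derl3 rose more in Flox (log2 -1.38, adjusted p = 0.0129). Cxcl2 (log2 1.27, adjusted p = 0.0212) and Hspa1a (log2 0.93, adjusted p = 0.0454) rose more in HKO. Cxcl2 started lower in HKO and stayed below Flox with PA. It measured 33.7 ± 4.84 and 52.2 ± 2.31 FPKM in Flox with BSA and PA, and 10.9 ± 1.98 and 42.8 ± 1.56 in HKO. Hspa1a measured 0.226 ± 0.0888 and 1.70 ± 0.283 FPKM in Flox, and 0.202 ± 0.0988 and 4.055 ± 0.564 in HKO.

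By list, 6 interaction lists passed at the preset correlation and 0 with an estimated one, where camera in limma gave 1 list an unadjusted p under 0.05. Their number was 14 with the GC trend removed, 14 without both HKO libraries numbered 1, 10 without HKO_BSA 1, and 1 with the self-contained test fry, which kept NF-kB targets and cytokines only. NF-kB targets and cytokines had a median of 0.49 (1 of 24 higher, 1 lower; 10 and 1 adjusted over the list alone). As a list, NF-kB targets and cytokines had adjusted p = 1.17e-06 and adjusted p = 0.388 with an estimated correlation; macrophage markers moved with them (median 0.44, 0 of 16 past, 7 higher adjusted over the list alone). Macrophage markers as a list had adjusted p = 0.00143 and adjusted p = 0.56 with an estimated correlation. Fatty acid synthesis had a median of -0.51 (0 of 17 past, 4 lower adjusted over the list alone; adjusted p = 3.43e-05) and glucose metabolism of -0.32 (0 of 15 past, 3 lower adjusted over the list alone; adjusted p = 0.0432), each with adjusted p = 0.56 with an estimated correlation. Ribosomal proteins had a median of 0.43 (0 of 75 past, 0 adjusted over the list alone; adjusted p = 2.16e-09, and adjusted p = 0.56 with an estimated correlation). Across genes the interaction ran against transcript length (Spearman -0.23), and HKO_PA 1 held 9.603% of its reads in ribosomal protein genes. OXPHOS subunits had 0.26 (0 of 49 past, 0 adjusted over the list alone; adjusted p = 0.0208, and adjusted p = 0.646 with an estimated correlation). The glucose call was lost without Flox_BSA 1 (0.0717), Flox_PA 2 (0.0863), HKO_BSA 2 (0.0977), HKO_PA 2 (0.0569) or HKO_PA 3 (0.0772), and with the length trend removed (0.0804). Replicate number as a block ended it too (0.0642). The OXPHOS call was lost without HKO_BSA 2 (0.305) or HKO_PA 1 (0.333) and with the length trend removed (0.132). With fry adjusted p was 0.111 for fatty acid synthesis, 0.49 for OXPHOS, 0.114 for glucose metabolism, 0.135 for macrophage markers and 0.23 for ribosomal proteins.

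The interaction had an unadjusted p under 0.05 in 1699 genes. In all, 26 genes passed, 16 with a higher and 10 with a lower PA effect in HKO than in Flox. The count rested on single libraries. With number as a block it was 15, and with genotype and number as a block 3. With limma it was 0 without Flox_PA 2 (1189 genes at an unadjusted p under 0.05), 6 without Flox_BSA 1, 9 without Flox_BSA 2, 16 without Flox_BSA 3, 11 without Flox_PA 3, 8 without HKO_BSA 2, 13 without HKO_BSA 3, 11 without HKO_PA 2 and 265 (77 higher, 188 lower) without HKO_PA 3, so none of the 12 named interaction genes passed with each library left out. It was 58 with quantile normalization, 10 with a filter at 5 FPKM, 63 with the length trend and 82 with the GC trend removed, 88 without both HKO libraries numbered 1, and 57 with default and 1668 (658 higher, 1010 lower) with gene-by-gene array weights.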

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

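The test of exchanged labels was chosen after the result was seen, and the counts of other splits were planned before. The results below stand out because the PA effect differed between the genotypes in the test of that difference, HKO minus Flox on the log2 scale.

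The gene G0s2 differed by 1.91, Lce1g by 1.52, Esm1 by 1.36, Clec7a by 1.35 and Pgf by 1.27. Clec7a fell with PA in Flox, from 8.27 ± 0.699 to 3.73 ± 0.436 FPKM. In HKO its means lay under 1 FPKM, at 0.188 ± 0.189 with BSA and 0.550 ± 0.286 with PA. Adam8 differed by -1.61, Ulk1 by -1.61, Csf1 by -1.39, Gclc by -1.39 and Derl3 by -1.38. None of the 12 named interaction genes passed with each library left out. By list, the median difference was -0.506 for fatty acid synthesis, 0.489 for NF-kB targets and cytokines, 0.261 for nuclear OXPHOS subunits, -0.32 for glucose metabolism, 0.439 for macrophage markers and 0.434 for cytosolic ribosomal proteins. These 6 lists passed at the preset correlation only: with an estimated correlation none passed, at adjusted p = 0.56, 0.388, 0.646, 0.56, 0.56 and 0.56 in that order.

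The HKO libraries were parted in a way that the BSA and PA labels do not describe. HKO_BSA 1 had 4091 FPKM of Alb, near HKO_PA 2 (6262) and HKO_PA 3 (5322), while HKO_PA 1 had 11720, near HKO_BSA 2 (15610) and HKO_BSA 3 (14050). Exchanged labels of HKO_BSA 1 and HKO_PA 1 are argued against by the genes that PA changed in Flox: the lowest HKO_PA score lay 0.51 (log2) above the highest HKO_BSA score, and Plin2 was 763.3 FPKM in HKO_PA 1 and 173.4 in HKO_BSA 1. A difference between cultures or preparations stays open, since the labels give no batch, and no biological explanation was tested.

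Of 100 splits for the interaction, the real one included, 3 gave at least the real count (26), so the share is under 0.05. Most other splits put BSA and PA libraries of 1 genotype into the same group, which adds the PA effects to the spread. Few calls are then built in, so this share does not test the interaction. Those of the 3 that were not the real split gave far more genes. The split that put HKO_BSA 1 with HKO_PA 2 and HKO_PA 3 gave 965 genes, which points to a structure of the HKO samples. The split with the PA labels of 1 genotype mirrored gave 395. It measures the sum of both PA effects, so its count says nothing about such a structure. For PA in HKO the real split gave 286 genes and the highest other, with the same parting of the HKO libraries, 240 (1 of 10 splits, the real one itself, gave as many). For PA in Flox the real split gave 215 genes and the highest other 0 (limma; 700 at an unadjusted p under 0.05), 1 of 10. For the knockout in BSA these counts were 1994 and 0 (limma; 1207 unadjusted), 1 of 10, and for the knockout in PA 3475 and 0 (limma; 237 unadjusted), 1 of 10. For these 4 comparisons, 10 splits are too few for a share under 0.05, and the other splits likewise mix libraries of both groups.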

How the results depend on the processing

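Voom on the computed reads, array weights gene by gene, the length and GC trends, and omission of both HKO libraries numbered 1 were chosen after seeing the data. G3bp1 stayed lower in HKO with each library of the groups compared left out, between -2.244 and -2.109 (log2) in BSA and between -2.316 and -2.227 in PA. Under trimmed mean scaling, a robust prior and voom every gene count stayed within 1.5 times the value of the report; voom shared 184, 258, 1934, 3379 and 16 genes with it, in the order PA in Flox, PA in HKO, knockout in BSA, knockout in PA and interaction. The counts that moved further are given in that order where they apply, and the cause was not tested except where named. Array weights by default, which did not converge, gave 4210, 117, 6016, 2307 and 57, and gene by gene 3641, 1532, 5764 for the first 3 and 1668 for the interaction. Omission of both HKO libraries numbered 1 gave 1356, 679, 3579 and, for the interaction, 88, and the GC trend removed 357, 687 and, for the interaction, 82. A fit with only the groups compared gave 1543 in Flox, whose libraries vary less, and 42 in HKO, whose libraries vary more; it does not apply to the interaction. The fold limit, which can only remove genes, gave 42, 60, 680 and 864. A pseudocount of 0.1 gave 142 for PA in Flox, no filter 144 for PA in HKO, and a filter at 5 FPKM, which tests fewer genes, 129 for PA in Flox, 1062 for the knockout in BSA and 10 for the interaction. Quantile normalization gave 58 and the length trend removed 63 for the interaction. Replicate number as a block gave 15 for the interaction, and genotype with number 110 for PA in Flox, 113 for PA in HKO and 3 for the interaction. The titles repeat genotype and number in both media, but name no shared mouse or day. Deviations of libraries with the same number correlated between -0.484 and 0.363, although in most Flox pairs and across genotypes the best partner had the same number. The numbers are therefore not treated as pairs. If they do mark pairs, the lower counts with genotype and number as a block apply. With the number as a block 3 list calls did not pass, glucose metabolism (0.0733) and stellate and matrix genes (0.0553) for the knockout in BSA and glucose metabolism in the interaction (0.0642). With 1 library of the groups compared left out the counts ranged from 64 to 169, 129 to 776, 1329 to 2376, 2280 to 4203 and 0 to 265. The lists called numbered 0, 1, 5, 2 and 0 with an estimated correlation (limma; 3 and 1 lists at an unadjusted p under 0.05 where the count is 0), 22 for the knockout in PA and 1 for the interaction with fry, which asks another question, and 14 for the interaction both with the GC trend removed and without both HKO libraries numbered 1; with 1 library left out they ranged from 10 to 16, 8 to 11, 20 to 23, 10 to 13 and 5 to 10. The slope of the PA response of HKO on Flox was 0.733 with a pseudocount of 0.1 and 0.492 with quantile normalization. Directions turned for the ribosomal list in BSA under quantile normalization (-0.019), Sorbs2 in PA with the GC trend removed (-0.034) and the mitochondrially encoded list for PA in HKO without both HKO libraries numbered 1 (-0.546, adjusted p = 0.00459); the cause was not tested. Alternatives for raw counts were not run, since the values are FPKM. In the simulation, which gave all genes and groups the same spread, a 1.5-fold change was recovered in 7.1% of genes in the interaction.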

Other observations

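All tests of the macrophage and Mup patterns were chosen after the results were seen.

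Antioxidant and stress genes moved both ways with the knockout in PA, as did the tested genes at large. Of all tested genes 35.7% passed there, 1644 higher and 1831 lower, so a list count near that share is no result about the list. Of 29 NRF2 targets and antioxidants 7 rose, 9 fell and 13 did not pass (8 and 9 adjusted over the list alone; list adjusted p = 0.91), with the glutathione transferase genes Gsta4 (log2 2.05) and Gsta2 (log2 2.04) highest. Of 22 ATF4 and CHOP targets 2 rose and 8 fell (2 and 8 adjusted over the list alone; list adjusted p = 0.315), among them Chac1 (log2 -0.91). Of 22 endoplasmic reticulum chaperones 2 rose and 4 fell (2 and 3 adjusted over the list alone; list adjusted p = 0.893), with a median log2 of -0.015 and a mean of 0.013. Of 20 p53 targets 1 rose and 3 fell (1 and 3 adjusted over the list alone; list adjusted p = 0.852), with a median of 0.049 against a mean of -0.052, the sign of the test. Of 11 cell cycle genes 3 rose and 1 fell (3 and 1 adjusted over the list alone; list adjusted p = 0.315). Of 15 early response genes 2 rose, Hspa1b (log2 1.14) and Hspa1a (log2 0.90), and none fell (2 adjusted over the list alone; list adjusted p = 0.552), with a median of -0.03 and a mean of 0.094. With PA, the stress factor gene Atf3 rose in Flox (log2 1.14) and in HKO (log2 1.19), and Ddit3, which encodes CHOP, rose in HKO (log2 0.89), while the ATF4 and CHOP list did not pass in either (adjusted p = 0.243 in Flox and 0.994 in HKO). Of 21 acute phase proteins Hamp and Steap4 (log2 1.28) rose with PA in Flox and none fell (3 adjusted over the list alone; list adjusted p = 0.111).

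In 158 genes every Flox library lay over 10-fold above every HKO library, and in 6 genes, all 6 of them Mup genes, every HKO library lay over 10-fold above every Flox library.

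Macrophage markers were lower in HKO libraries, all 16 of them by more than 4-fold in both media (100%), and a candidate explanation is fewer macrophages among the HKO cells. Abundant markers such as Cd5l (297 FPKM in Flox_BSA and 7.15 in HKO_BSA) fell together, and no member is on another list. For a loss of every other cell type alike, the endothelial median was -0.493, above the macrophage marker that fell least (-2.099). Endothelial genes near 2 FPKM, such as Lyve1 (1.90 in Flox_BSA), cannot fall that far on this scale, so the median alone does not decide this. Stab1 and Cdh5, at 8.44 and 7.66 FPKM in Flox_BSA, could fall that far. Their log2 changes in BSA were -1.71 and -1.13, which argue against such a loss for these genes. Scaling is argued against by the macrophage list's median of -3.406 nearest to 0 under other scalings. For interferon response genes the median nearest to 0 was -1.293, outside the range of the markers, and since hepatocytes express these genes too, fewer macrophages and a change within hepatocytes cannot be told apart for them. The neutrophil genes (medians -2.913 in BSA and -3.177 in PA, 2 genes) and Ccl5 of the lymphocyte list (-3.564 and -2.671) fell about as far, so a loss of immune cells more widely stays open, as does whether the difference arose in the liver of the knockout mice or in the preparation of the cells.

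Mup genes were higher in HKO, and 3 technical explanations were examined. Reads split differently between copies would leave their sum over 21 genes alike only if reads matching several copies were kept. The lowest HKO sum was 5.1 times the highest Flox sum, which argues against such a split in that case. The read counter is not given in the sources used here. If such reads were dropped, the sum could change as well, so a difference in how reads were assigned stays open. A larger hepatocyte share would raise Mup genes no further than other hepatocyte genes, but the sum rose by at least 2.955 (log2) in both media, against at most 1.565 for a hepatocyte identity gene. A difference in sex is argued against by Eif2s3y of at least 1.94 FPKM and Xist of 0 in all 12 libraries. An effect of genotype may remain as a hypothesis, while batch, strain background and the housing of the mice, which the labels do not give, stay open.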
